A study of Homo sapiens with 22 samples.

How the data were processed

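RNA of 22 MDA-MB-231 libraries in 11 groups of 2 was sequenced. Per the labels' protocols, cells grew in DMEM with 10% FBS, were infected with lentivirus and/or given drugs, and RNA was taken with Trizol. The protocols describe 2 library preparations without saying which samples each applies to, a directional kit run on a HiSeq 3000, and a depletion of ribosomal RNA followed by poly(A) minus or plus fractions run on a HiSeq X-Ten. Per the submitters' processing notes, CASAVA 1.4, HISAT2 2.1.0 and Cufflinks 2.2.1 were used with the hg38 genome. The notes give no role or order for these tools, and options, annotation and the use of strand are not given in the sources used here.

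The authors deposited 3 tables of FPKM (fragments scaled to gene length and to the total of the library). FPKM stands in the name of 1 table only, and for the others the unit was inferred from the format and the sums. The FPKM of a library summed to between 426106 and 469180, except in B5 replicate 2, where PIDD1 alone was listed at 8234200 and the other genes summed to 423171. Depth per library is therefore unknown, apart from the rough step of the lowest values given with the results, and no interval that needs counts is given. The knockdown and DMSO tables hold 60669 genes each. The CTRL table holds 14954, those with a result in columns of the authors' own test, which give a log2 fold change and its standard error, p-values and adjusted p-values, and a mean signal per gene, per the file headers. The name of the file sets MW against JQ1, while the deposited log2 fold change names no groups or direction. Of that table's contrasts it followed JQ1 against CTRL best (r = 0.635 over its calls, 91.2% of one sign, 0.483 over all genes). For MW_JQ1 against JQ1 r was -0.386 over its calls, and for MW_JQ1 against CTRL 0.337. The change is read as JQ1 against CTRL, with doubt. No per-sample column was left unused.

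The tests, lists, alternatives and the rule for named genes were set before the data were examined. The design allowed for counts or FPKM, and since the unit is FPKM the test planned for normalized values was used. FPKM was taken as log2(FPKM + 1), genes at 1 FPKM or more in at least 2 libraries of a table were kept (14638, 14936 and 13261 genes), and all groups of a table were fitted together with limma 3.58.1 (lmFit, contrasts, eBayes with trend) in R 4.3.3. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. There were 14 comparisons, 6 of them main. Each was tested within 1 table. Figures and summaries used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

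The 29 gene lists covered the m6A writer complex, m6A erasers and readers, other RNA methyltransferases, BET proteins and partners, BET inhibitor response markers, elongation factors, RNA polymerase II and general factors, MYC targets, S phase, G2/M, DNA repair by recombination, interferon-stimulated genes, antigen presentation, NF-kB and inflammatory cytokine genes, AP-1 and immediate early genes, extracellular matrix and EMT, p53 targets, the unfolded protein and ATF4 response, cholesterol synthesis, glycolysis and hypoxia, cytosolic ribosomal proteins, oxidative phosphorylation, mitochondrial genome transcripts, replication-dependent histones, apoptosis regulators, markers of luminal epithelium, of haematopoietic cells and of fibroblasts and endothelium, and nuclear retained and small structured RNAs. Each was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and fry as alternatives. Lists with at least 3 members tested were used. Camera compares a list with the other genes, and fry asks whether its genes move one way.

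Named genes included METTL3, METTL14, WTAP, MYC, HEXIM1 and BRD2 in some comparisons. To these were added the 6 highest rises and 6 deepest falls of each main comparison, or 3 and 3 of the others, among genes past the threshold with both libraries of one group above both of the other and a mean of at least 5 FPKM. In the main comparisons, each list described gave up to 4 members with the smallest adjusted p, or, where none passed, the 2 with the highest mean. List members named in the other comparisons, and members chosen to follow a gene from one comparison to the next, lie outside this rule and were chosen after their values were seen. So were the 13 genes whose Molib minus JQ1 intervals were computed. Locations are those of the GENCODE annotation of hg38, matched by gene ID. XIST and Y-linked genes are not reported by level.

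Alternatives changed 1 choice, but a replicate block also dropped JQ1 of the DMSO table. They were a replicate block, a fit of the contrast's groups alone, pseudocounts of 0.1 and 5, no filter beyond a value above 0 in 2 libraries, a filter at 5 FPKM, TMM factors computed by hand without weights (trims of 30% and 5%), scaling to equal medians, a further 2-fold limit, and leaving out each of the 22 libraries. A group left with 1 library took the spread of the others. Added after seeing the data were array weights, protein-coding genes only, genes above 0 in all 6 libraries of the CTRL table, the knockdown table without mitochondrial genes and PIDD1, the DMSO table without the libraries labelled I-BET151, calls of JQ1 from the DMSO table for the reversal by MW, and the count of each list under the other scalings.

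The fits were tested on simulated data with 200 changed genes drawn on the real means and spread. In the knockdown table (shM3 against B5, 14638 genes) 0%, 88%, 99% and 100% of genes changed by 1.5, 2, 4 and 16-fold were called, and in the DMSO table (Molib against DMSO, 14936 genes) 0%, 85.5%, 99.5% and 100%. In the CTRL table (JQ1 against CTRL, 13261 genes) 0% were called at 1.5, 2 and 4-fold and 30% at 16-fold, a size added after the smaller ones gave no call. All 5 changed lists of 20 were called in each table and none of the unchanged. Chance values for comparisons that share libraries came from 100 simulated draws.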

Results

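Gene expression was measured by RNA-seq in 22 libraries of MDA-MB-231, an established human breast cancer cell line, in 11 groups of 2 libraries each. The series title sets inhibition of BET proteins, the bromodomain readers of acetylated histones, beside the m6A writer complex, which methylates adenosines in RNA and has METTL3 as its catalytic subunit. The libraries came in 3 tables. The knockdown table held cells labelled B5, cells labelled shM3, and shM3 cells with METTL3-WT or METTL3-CD added back (shM3_WT and shM3_CD), all kept for 2 to 3 months. The DMSO table held cells given DMSO, JQ1, Molib or I-BET151, each compound at 0.5 µM for 3 days. The CTRL table held CTRL cells, cells given 0.5 µM JQ1 and cells labelled MW_JQ1, also given 0.5 µM JQ1, all for 3 days, and the labels do not say what MW stands for. In the DMSO table the JQ1 columns share their names with JQ1 samples of the CTRL table. They were taken as the other JQ1 samples by elimination, carry no replicate number and are called libraries a and b. Read totals were not among the deposited values. If the commonest lowest step of FPKM stands for 1 fragment, the 16 libraries of the knockdown and DMSO tables would hold 13.3 to 18.8 M (1e6) fragments, which is a rough guide only.

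Levels below are FPKM as mean ± SD (n = 2 libraries). Fold changes on the log2 scale are differences of log2(FPKM + 1), which understate the change of low genes, and every adjusted p is from limma with Benjamini-Hochberg adjustment. Tests were made within a table only, because the sources used here do not say whether the tables were processed together. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

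METTL3 (ENSG00000165819, hg38 chromosome 14, 21498133 to 21511375, minus strand) was the targeted gene and was read first in every library. In the knockdown table it was at 20.1 and 23.8 FPKM in B5, 4.39 and 4.80 in shM3, 312 and 311 in shM3_WT, and 277 and 270.5 in shM3_CD. In the DMSO table METTL3 was at 25.4 and 27.2 in DMSO, 20.1 and 19.2 in JQ1, 21.5 and 19.7 in Molib, and 18.3 and 13.7 in the libraries labelled I-BET151. In the CTRL table METTL3 was at 31.2 and 1.18 in CTRL, 11.8 and listed at 0 in JQ1, and 212 and 234 in MW_JQ1.

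**Figure D1:**
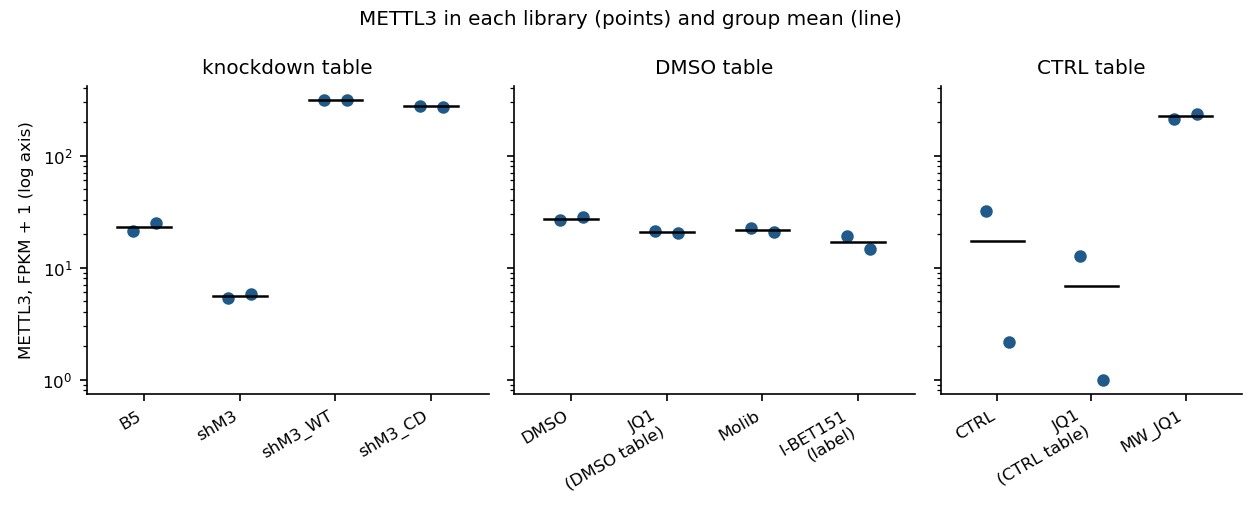
METTL3 in each of the 22 libraries (points, FPKM + 1 on a log axis) and its group mean (line), with 1 panel per table. METTL3 was 4.60 ± 0.293 in shM3 against 21.9 ± 2.64 in B5, lay above 200 FPKM in shM3_WT, shM3_CD and MW_JQ1, and differed between the 2 libraries of CTRL and of JQ1 in the CTRL table.

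The first comparison asked what lowering METTL3 did to the transcriptome. METTL3 was 4.77-fold lower in shM3 than in B5 (4.60 ± 0.293 against 21.9 ± 2.64 FPKM, log2 fold change -2.03, SE 0.09, adjusted p = 3.4e-05). The cell cycle genes fell together. Of 41 S phase genes tested, 36 fell and 1 rose (median log2 fold change -0.98), and of 38 G2/M genes 36 fell and none rose (median -1.12). TYMS, which makes thymidylate for DNA synthesis, was 4.96-fold lower (21.1 ± 0.972 against 104 ± 9.02), and E2F1, a transcription factor of S phase entry, 4.22-fold lower (9.55 ± 0.606 against 40.3 ± 3.55). TOP2A, which untangles replicated DNA, fell to 30.1 ± 0.476 from 118 ± 12.5, and the spindle factor TPX2 to 33.8 ± 0.0542 from 96.1 ± 1.16. Of 25 genes of DNA repair by recombination 20 fell and none rose (median -0.70), among them FANCI (2.52-fold lower) and the exonuclease gene EXO1 (3.62-fold lower). Camera called S phase (adjusted p = 1.4e-15) and G2/M (1.3e-18), and both held with an estimated correlation (adjusted p = 0.012 for each). It also called DNA repair (4.5e-07), but not with an estimated correlation (adjusted p = 0.077 with an estimated correlation). Adjusted over the list alone, 37 S phase genes fell and 1 rose, 37 G2/M genes fell, and 21 DNA repair genes fell and 1 rose.

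Antigen presentation genes fell with the knockdown as well. Of 26 tested, 22 fell and none rose (22 adjusted over the list alone, median -0.91, camera adjusted p = 1.6e-12, adjusted p = 0.012 with an estimated correlation). HLA-DRA (ENSG00000204287, chromosome 6, 32439842 to 32445046, plus strand), a chain of the class II antigen-presenting molecule, was 12.3-fold lower in shM3 (17.5 ± 0.765 against 216 ± 12.7). HLA-DPA1 was 8.16-fold lower (6.42 ± 0.332 against 52.4 ± 4.20) and CD74, the invariant chain, 4.15-fold lower (121 ± 1.97 against 501 ± 39.2). Of 44 extracellular matrix and EMT genes 25 fell and 9 rose (26 and 11 adjusted over the list alone, median -0.53, camera adjusted p = 0.0015, adjusted p = 0.13 with an estimated correlation). Fibronectin, FN1, was 4.08-fold lower (42.4 ± 3.94 against 173 ± 6.96) and the protease inhibitor gene TIMP3 2.68-fold lower (125 ± 2.07 against 334 ± 7.07). Of 6 fibroblast and endothelial markers 5 fell (1 higher and 5 lower adjusted over the list alone, median -0.67). Of 29 genes of RNA polymerase II and general factors, 9 rose and 1 fell (also 9 and 1 adjusted over the list alone, median 0.24, camera adjusted p = 0.022, adjusted p = 0.29 with an estimated correlation). POLR2A, the largest polymerase subunit, rose 1.59-fold (66.1 ± 1.69 against 41.6 ± 2.94) and the helicase gene ERCC2 1.81-fold. Of 30 glycolysis and hypoxia genes 11 rose and 3 fell (15 and 3 adjusted over the list alone, camera adjusted p = 0.043, adjusted p = 0.24 with an estimated correlation). BNIP3 rose 2.46-fold and VEGFA, a growth factor of blood vessels, was 2.11-fold lower. Of 6 haematopoietic markers 4 fell and none rose (also 4 adjusted over the list alone, median -1.08, camera adjusted p = 0.034, adjusted p = 0.29 with an estimated correlation), among them LAPTM5, 4.68-fold lower.

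The highest rises by the naming rule included UCA1, a long noncoding RNA (11.7-fold, 11.2 ± 1.90 against 0.956 ± 0.326), CHAC1, a glutathione-degrading enzyme of the ATF4 response (8.01-fold), the histone gene H2BC4 (7.68-fold), the keratin-associated KRTAP2-3 (7.39-fold) and VAMP3, a membrane fusion protein (5.96-fold). Among the falls were the nerve growth factor receptor gene NGFR (26.7-fold lower, 2.76 ± 0.396 against 73.6 ± 0.00641), the VIP receptor gene VIPR1 (14.3-fold), the organic anion transporter gene SLCO4A1 (12.6-fold) and the matricellular CCN3 (11.3-fold). Of the writer complex's other named subunits, METTL14 fell to 5.04 ± 0.130 from 9.18 ± 1.23 (log2 fold change -0.75, adjusted p = 0.011), a call lost without B5 replicate 2 (adjusted p = 0.0596) or shM3 replicate 1 (0.0563), and WTAP was 24.4 ± 1.32 against 26.9 ± 0.174 (adjusted p = 0.32). In all, 7 writer genes were tested, of which 1 rose and 2 fell (1 and 2 adjusted over the list alone). HEXIM1 was 45.9 ± 1.74 against 42.8 ± 1.96 (adjusted p = 0.46). BRD2 was 58.3 ± 0.461 against 68.1 ± 1.87 (adjusted p = 0.047), a call lost without any 1 of B5 replicate 1 (0.0674), B5 replicate 2 (0.13), shM3 replicate 1 (0.16) or shM3 replicate 2 (0.136), and also with median scaling (0.0729). MYC was 7.39 ± 0.195 in shM3 and 14.1 ± 14.7 in B5 (adjusted p = 0.68), and it was called higher without B5 replicate 2 (adjusted p = 0.0223) and lower without B5 replicate 1 (0.00276). In all, 5534 of 14638 genes passed the threshold, 2620 higher and 2914 lower in shM3 (2883 and 2729 with median scaling), and 1134 of them by at least 2-fold (315 higher, 819 lower). Without shM3 replicate 1 the count was 3654, and without shM3 replicate 2 it was 3683.

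The add-back groups asked which of these differences returned with METTL3. In shM3_WT, METTL3 was 67.8-fold above shM3 (312 ± 0.608 FPKM, adjusted p = 8.7e-07), and the cell cycle genes rose. All 38 G2/M genes rose (38 adjusted over the list alone, median 1.58) and 39 of 41 S phase genes rose while 1 fell (39 and 1 adjusted over the list alone, median 1.102). TYMS rose 4.68-fold to 98.7 ± 0.989, E2F1 4.09-fold to 39.1 ± 1.59, TPX2 4.01-fold to 135 ± 1.87 and the mitotic cyclin CCNB1 3.72-fold to 179 ± 0.509. Interferon-stimulated genes went down, with 37 of 39 lower (38 adjusted over the list alone, median -1.53). This was not a return, since 4 of these genes were higher and 15 lower in shM3 against B5 (median -0.20). The antiviral genes MX1, IFIT1 and OAS1 were 7.51-fold, 6.48-fold and 10.2-fold lower in shM3_WT than in shM3. Camera called these 3 lists with the preset and the estimated correlation (estimated adjusted p = 0.0058 for G2/M, 0.0065 for S phase and 0.0063 for interferon-stimulated genes). Nuclear retained and small structured RNAs, a check on the RNA fraction, fell in 6 of 9 cases and rose in 1 (also 6 and 1 adjusted over the list alone, median -1.23, camera adjusted p = 0.15), with 4 lower under TMM factors or median scaling.

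Antigen presentation genes rose in shM3_WT in 17 of 26 cases and fell in 2 (18 and 2 adjusted over the list alone, adjusted p = 0.015 with an estimated correlation), with HLA-DRA 8.56-fold higher (150 ± 2.88) and HLA-DPA1 6.64-fold higher (42.6 ± 1.57). Of 34 NF-kB and inflammatory cytokine genes 21 rose and 2 fell (22 and 2 adjusted over the list alone, adjusted p = 0.013 with an estimated correlation). The cytokine genes CSF2 (20.9-fold, 116 ± 2.71 against 5.55 ± 1.02), CSF3 (19.4-fold) and CXCL8 (18.2-fold, 353 ± 3.19 against 19.4 ± 0.201) and the complement gene C3 (13.1-fold) were among them. Of 25 cholesterol synthesis genes 15 fell and 1 rose (16 and 1 adjusted over the list alone, camera adjusted p = 5.2e-05, adjusted p = 0.064 with an estimated correlation), with the sterol oxidase MSMO1 3.48-fold lower. H2BC4 fell 12.1-fold and IGFBP6, a binding protein of insulin-like growth factors, 8.53-fold (45.5 ± 2.87 against 388 ± 5.25), while the ribosomal protein gene RPS24 rose 5.81-fold. HEXIM1, the inhibitor of the elongation factor P-TEFb, was 26.9 ± 2.55 in shM3_WT against 45.9 ± 1.74 (1.71-fold lower, adjusted p = 0.0012), and METTL14 was 6.01 ± 1.54 against 5.04 ± 0.130 (adjusted p = 0.38). In all, 5772 genes passed the threshold, 2451 higher and 3321 lower as deposited, but 2899 and 2648 with TMM factors and 2886 and 2690 with median scaling.

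In shM3_CD, METTL3 was 59.5-fold above shM3 (274 ± 4.47, adjusted p = 1.1e-06). Of 38 G2/M genes 29 rose and none fell (36 adjusted over the list alone, median 0.77), and of 41 S phase genes 19 rose and 1 fell (31 and 1 adjusted over the list alone, median 0.44). The kinesin gene KIF2C rose 2.21-fold (34.6 ± 0.632 against 15.7 ± 1.35). NF-kB and inflammatory cytokine genes rose in 20 of 34 cases and fell in 2 (22 and 2 adjusted over the list alone), with LCN2, a siderophore-binding protein of inflammation, 26.3-fold higher (44.3 ± 1.99 against 1.69 ± 0.831), C3 23.0-fold, CSF3 22.3-fold and CXCL8 9.01-fold. Antigen presentation genes rose in 12 of 26 cases (13 adjusted over the list alone), with HLA-DRA 6.05-fold and HLA-DPA1 5.37-fold higher. Interferon-stimulated genes fell in 19 of 39 cases and rose in 1 (22 and 2 adjusted over the list alone), among them MX1, 4.24-fold lower. Here too, more of these genes had been lower than higher in shM3 against B5 (15 and 4). Glycolysis and hypoxia genes rose in 11 of 30 cases and fell in 1 (16 and 2 adjusted over the list alone), with VEGFA 2.31-fold higher (146 ± 0.185). These 6 lists held with an estimated correlation (adjusted p between 0.0086 and 0.034). Nuclear retained and small structured RNAs fell in 2 of 9 cases (3 adjusted over the list alone, median -0.71, camera adjusted p = 0.078). H2BC4 fell 5.08-fold, and KISS1, a metastasis suppressor gene, 4.55-fold. In all, 1670 genes passed the threshold, 998 higher and 672 lower, against 527, 569, 500 and 527 without shM3 replicate 1, shM3 replicate 2, shM3_CD replicate 1 and shM3_CD replicate 2.

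Of the 5534 genes called in shM3, 83.5% had the opposite sign in shM3_WT against shM3 and 79.1% in shM3_CD against shM3. In shM3_WT, 3048 of them were called in the opposite direction and 259 in the same direction, and in shM3_CD 1079 and 102. The median share of the change that was undone was 66.1% in shM3_WT and 31.6% in shM3_CD. These comparisons share the shM3 libraries, and 100 simulated draws with no add-back effect gave a mean of 57.1% with the opposite sign (at most 58.6%), a mean median share of 3.16% and at most 2 genes called in the opposite direction.

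Set directly against each other, shM3_WT and shM3_CD had METTL3 at 312 ± 0.608 and 274 ± 4.47 FPKM (log2 fold change 0.19, adjusted p = 0.18), a difference that was called with median scaling (0.30, adjusted p = 0.046). The cell cycle genes were higher in shM3_WT, with 35 of 41 S phase genes (37 adjusted over the list alone, median 0.52) and 36 of 38 G2/M genes (also 36 adjusted over the list alone, median 0.81) higher and none lower. TYMS was 2.34-fold higher and the mitotic regulator CDC20 2.45-fold higher (254 ± 3.57 against 104 ± 1.49). Interferon-stimulated genes were lower in shM3_WT in 30 of 39 cases (32 adjusted over the list alone, median -1.01), with IFIT1 5.60-fold lower (7.43 ± 0.401 against 41.6 ± 1.53) and OASL 4.59-fold lower. Of 53 MYC targets 16 were higher and 2 lower (18 and 2 adjusted over the list alone), among them TCOF1, a factor of ribosomal RNA synthesis, at 2.28-fold. These 4 lists held with an estimated correlation (adjusted p = 0.0073, 0.0067, 0.0073 and 0.029 in the order given). Cholesterol synthesis genes were lower in 14 of 25 cases and higher in 2 (16 and 2 adjusted over the list alone, adjusted p = 0.088 with an estimated correlation), with MSMO1 2.99-fold lower. Glycolysis and hypoxia genes were lower in 14 of 30 cases and higher in 1 (17 and 1 adjusted over the list alone, adjusted p = 0.079 with an estimated correlation), with NDRG1 2.96-fold lower.

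NF-kB and inflammatory cytokine genes went both ways between shM3_WT and shM3_CD, 8 higher and 8 lower (9 and 10 adjusted over the list alone), and their median changed sign with the scaling (-0.02 as deposited, 0.08 with TMM factors). CXCL8 was 2.02-fold and PTX3 2.14-fold higher in shM3_WT, and C3 1.76-fold lower. MPZL1, a membrane receptor gene, was 5.97-fold higher (38.2 ± 7.87 against 6.39 ± 1.28), the secreted trefoil factor TFF1 4.86-fold and the collagenase MMP1 4.11-fold (419 ± 7.87 against 102 ± 0.476), while HEXIM1 was 1.62-fold lower (adjusted p = 0.0039). In all, 3785 genes passed the threshold, 1494 higher and 2291 lower, so 39.5% were higher as deposited. With TMM factors 55.4% were higher (1944 and 1566), and with median scaling 57.3% (2014 and 1501). The count was 1955 without shM3_WT replicate 1, 1826 without shM3_WT replicate 2, 1783 without shM3_CD replicate 1 and 1781 without shM3_CD replicate 2. Of the knockdown's calls, 2178 also differed between the add-back groups, 1828 of them with shM3_WT further from the direction of the knockdown and 350 with shM3_CD further.

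The DMSO table asked what 3 BET inhibitors did at the same dose and time. JQ1, a thienodiazepine that occupies BET bromodomains, raised HEXIM1 (ENSG00000186834, chromosome 17, 45148502 to 45152101, plus strand) 2.69-fold, to 75.3 ± 2.05 from 27.9 ± 2.01 (adjusted p = 0.0017), and BRD2 (ENSG00000204256, chromosome 6, 32968660 to 32981505, plus strand) 3.39-fold, to 219.5 ± 6.40 from 64.7 ± 0.224 (adjusted p = 2.7e-05). Histone genes were among the highest rises. H2BC4 (ENSG00000180596, chromosome 6, 26114873 to 26123926, minus strand) rose 58.6-fold (50.2 ± 1.76 against 0.857 ± 0.00836), H2BC5 24.2-fold (229.6 ± 5.65 against 9.48 ± 0.948) and H2AC6 21.3-fold (158 ± 4.58 against 7.43 ± 0.461). H2AC18 and H2AC19 rose to 152 ± 0.146 and 148 ± 0.238, but they are near-identical copies whose reads may be split between them, so each value is uncertain. The noncoding AP000692.2 rose to 23.4 ± 0.226 from 0.220 ± 0.211, and is uncertain where another gene overlaps it, since the use of strand in counting is not stated. Among 18 BET inhibitor response markers 11 rose and 4 fell (11 and 5 adjusted over the list alone, median 1.01, camera adjusted p = 0.00045, adjusted p = 0.14 with an estimated correlation), and of 13 replication-dependent histones 7 rose and none fell (also 7 adjusted over the list alone, median 0.74, adjusted p = 0.18 with an estimated correlation), among them H3C10 (10.6-fold) and H2BC6 (16.99-fold). Nuclear retained and small structured RNAs, a check on the RNA fraction, rose in 5 of 9 cases and fell in none (also 5 adjusted over the list alone, median 0.38, camera adjusted p = 0.011, adjusted p = 0.38 with an estimated correlation).

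Inflammatory genes fell the furthest with JQ1. Of 36 NF-kB and inflammatory cytokine genes 26 fell and none rose (29 fell and 1 rose adjusted over the list alone, median -1.10, camera adjusted p = 2.6e-13, adjusted p = 0.013 with an estimated correlation). CSF3 was 117-fold lower (1.06 ± 0.0359 against 123 ± 4.97), CSF2 (ENSG00000164400, chromosome 5, 132073790 to 132076170, plus strand) 67.8-fold lower (1.09 ± 0.0590 against 73.8 ± 3.58), IL1B 25.4-fold, CXCL8 10.8-fold and CXCL1 8.05-fold. SLCO4A1 was 32.5-fold and the epithelial transcription factor SPDEF 38.5-fold lower. Of 41 S phase genes 39 fell (40 adjusted over the list alone, median -1.003, adjusted p = 0.013 with an estimated correlation), including the replicative helicase genes MCM5 (4.46-fold lower, 10.9 ± 0.129 against 48.6 ± 0.216) and MCM2 (3.397-fold) and E2F1 (3.63-fold). Of 38 G2/M genes 32 fell (also 32 adjusted over the list alone, median -1.04, camera adjusted p = 1.2e-13, adjusted p = 0.12 with an estimated correlation), with TPX2 3.199-fold and the proliferation marker MKI67 3.76-fold lower. Of 25 DNA repair genes 12 fell and 1 rose (13 and 1 adjusted over the list alone, adjusted p = 0.47 with an estimated correlation), and of 26 apoptosis regulators 13 fell, among them BCL2A1, 9.06-fold lower, and 1 rose (15 and 2 adjusted over the list alone, adjusted p = 0.12 with an estimated correlation).

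AP-1 and immediate early genes rose in 12 of 25 cases and fell in 4 with JQ1 (13 and 5 adjusted over the list alone, adjusted p = 0.28 with an estimated correlation), led by the growth factor CCN2, 7.94-fold higher at 547 ± 1.44. Extracellular matrix and EMT genes fell in 25 of 44 cases and rose in 9 (26 and 10 adjusted over the list alone, adjusted p = 0.12 with an estimated correlation). Markers of fibroblasts and endothelium fell in 3 of 5 cases (4 adjusted over the list alone, median -0.64, camera adjusted p = 0.079). The urokinase gene PLAU was 4.78-fold and TIMP3 3.35-fold lower, and MMP1 4.03-fold higher. POLR2A rose 1.98-fold (115 ± 1.62 against 58.2 ± 0.616), and the histone methyltransferase gene NSD2 was 2.48-fold lower. Of the 8 writer genes 2 fell (also 2 adjusted over the list alone, median -0.37, camera adjusted p = 0.05, adjusted p = 0.38 with an estimated correlation). METTL14 (ENSG00000145388, chromosome 4, 118685368 to 118715433, plus strand) was 1.98-fold lower (5.34 ± 0.377 against 10.6 ± 1.41, adjusted p = 0.019), and CBLL1 1.91-fold lower (adjusted p = 0.0083). METTL3 was 19.7 ± 0.646 against 26.3 ± 1.28 (log2 fold change -0.40, SE 0.14, adjusted p = 0.062), and WTAP 26.4 ± 1.33 against 31.7 ± 1.49 (adjusted p = 0.092, called at 0.0462 with array weights). MYC was 4.68 ± 1.76 against 4.56 ± 0.981 (adjusted p = 0.99). The METTL14 call was lost without DMSO replicate 1 (adjusted p = 0.105), DMSO replicate 2 (0.0512), library a (0.0655) or library b (0.0922), and that of CBLL1 without library b (0.0562). METTL3 was called when these groups alone were fitted (adjusted p = 0.019), and in settings chosen after seeing the data, without the libraries labelled I-BET151 in the fit (0.0132) or with array weights (0.0172). In all, 5238 of 14936 genes passed the threshold, 2168 higher and 3070 lower, against 3047, 2891, 2854 and 2997 without DMSO replicate 1, DMSO replicate 2, library a and library b.

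**Figure D2:**
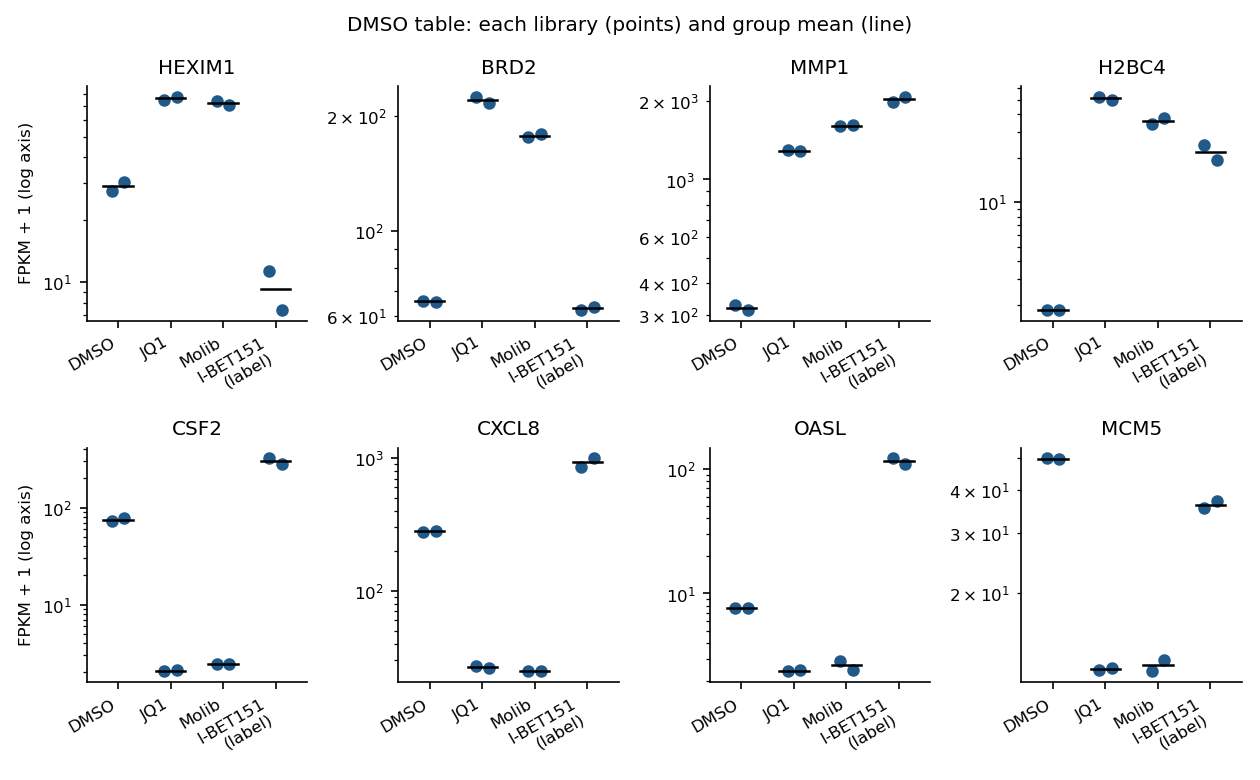
HEXIM1, BRD2, MMP1, H2BC4, CSF2, CXCL8, OASL and MCM5 in each library of the DMSO table (points, FPKM + 1 on a log axis) with the group mean (line). HEXIM1 was 75.3 ± 2.05 with JQ1, 71.3 ± 2.32 with Molib and 8.34 ± 2.78 in the libraries labelled I-BET151, against 27.9 ± 2.01 with DMSO, while MCM5 was lower than with DMSO in all 3.

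Molib was set against the same DMSO libraries. HEXIM1 rose 2.55-fold (71.3 ± 2.32, adjusted p = 0.0019) and BRD2 2.73-fold (177 ± 2.45, adjusted p = 5.9e-05). H2BC4 rose 40.8-fold (34.96 ± 2.22), H2BC5 19.9-fold (189 ± 6.32), H2AC6 18.2-fold (135 ± 5.09), H3C10 9.25-fold, H2BC6 13.6-fold and AP000692.2 to 24.3 ± 1.38. CSF3 was 72.8-fold lower (1.70 ± 0.274), CSF2 50.7-fold (1.46 ± 0.00208), IL6 27.1-fold (0.988 ± 0.269 against 26.8 ± 3.18) and CXCL8 11.7-fold (23.9 ± 0.191). SLCO4A1 was 30.9-fold, SPDEF 35.6-fold and PLAU 5.01-fold lower, while CCN2 rose 10.2-fold and MMP1 5.03-fold. Of 36 NF-kB and inflammatory cytokine genes 26 fell (27 adjusted over the list alone, median -1.02, adjusted p = 0.012 with an estimated correlation), and of 41 S phase genes 39 (41 adjusted over the list alone, median -1.20, adjusted p = 0.012 with an estimated correlation). Of 38 G2/M genes 34 fell (35 adjusted over the list alone, adjusted p = 0.098 with an estimated correlation), with the kinase gene AURKA 3.89-fold and the kinetochore gene NDC80 4.92-fold lower. TYMS was 5.36-fold lower (22.5 ± 1.55 against 121 ± 3.56), and MCM5 4.34-fold lower. Of the response markers 11 of 18 rose and 3 fell (also 11 and 3 adjusted over the list alone, adjusted p = 0.13 with an estimated correlation), and of the replication-dependent histones 7 of 13 rose (also 7 adjusted over the list alone, adjusted p = 0.19 with an estimated correlation). Nuclear retained and small structured RNAs rose in 3 of 9 cases (also 3 adjusted over the list alone, median 0.13, camera adjusted p = 0.083).

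Of the 8 writer genes 4 fell with Molib (also 4 adjusted over the list alone, median -0.46, camera adjusted p = 0.053). WTAP (ENSG00000146457, chromosome 6, 159725585 to 159756319, plus strand), which anchors the writer complex, was 1.41-fold lower (22.5 ± 1.43, adjusted p = 0.011), ZC3H13 1.399-fold (9.03 ± 0.888 against 12.6 ± 0.0128, 0.017), CBLL1 1.62-fold (4.31 ± 0.420, 0.023) and VIRMA 1.45-fold (11.5 ± 0.0344 against 16.7 ± 3.45, 0.045). The WTAP call was lost without DMSO replicate 2 (adjusted p = 0.0728) or Molib replicate 2 (0.0739), and that of ZC3H13 without DMSO replicate 1 (0.0782), DMSO replicate 2 (0.0779) or Molib replicate 2 (0.107). The CBLL1 call was lost without DMSO replicate 1 (0.105), DMSO replicate 2 (0.0841), Molib replicate 1 (0.118) or Molib replicate 2 (0.0598), and that of VIRMA without DMSO replicate 1 (0.234), Molib replicate 1 (0.143) or Molib replicate 2 (0.139). VIRMA was also not called with TMM factors (0.0525), median scaling (0.0579), these groups alone (0.0586), no filter (0.0871) or the replicate block (0.0993). METTL3 was 20.6 ± 1.21 (adjusted p = 0.10, called at 0.0399 with these groups alone, 0.0235 without the libraries labelled I-BET151 in the fit and 0.0378 with array weights), and METTL14 6.98 ± 2.28 (adjusted p = 0.080, called at 0.0291 without Molib replicate 1 and 0.0435 with the replicate block). MYC was 5.14 ± 0.993 (adjusted p = 0.67), and POLR2A rose 1.90-fold (111 ± 0.291). In all, 5273 genes passed the threshold, 2217 higher and 3056 lower, against 3077, 3056, 3250 and 3170 without DMSO replicate 1, DMSO replicate 2, Molib replicate 1 and Molib replicate 2.

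Compared directly at the same dose and time, Molib and JQ1 gave no gene past the threshold in limma (1227 genes had an unadjusted p under 0.05, array weights called 2 genes, and 1 gene was called without Molib replicate 2 or library a). The 95% interval of the log2 difference, Molib minus JQ1, was -0.52 to 0.36 for HEXIM1, -0.50 to -0.12 for BRD2, -0.27 to 0.39 for METTL3 and -0.20 to 0.81 for METTL14. For H2BC4 it was -0.81 to -0.20, for CSF3 0.11 to 0.66, for CCN2 0.18 to 0.55, for CXCL8 -0.34 to 0.12 and for MCM5 -0.19 to 0.25. Of the 6315 genes called with either compound, 96.0% had an interval within 1 log2 unit of 0, and the median half-width was 0.33. A missed threshold does not show that the compounds act alike, and differences smaller than these intervals remain possible. Camera with the preset correlation called 4 lists, all with small medians, and none held with an estimated correlation. These were G2/M (-0.15, adjusted p = 0.71 with an estimated correlation), DNA repair (-0.10, 0.86), cholesterol synthesis (0.12, 0.48) and glycolysis and hypoxia (-0.12, 0.48).

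The libraries labelled I-BET151 differed from JQ1 and Molib in several of these genes. HEXIM1 was 3.35-fold lower than with DMSO (8.34 ± 2.78, adjusted p = 0.0011), and BRD2 was 62.0 ± 0.915 against 64.7 ± 0.224 (adjusted p = 0.61). Interferon-stimulated genes rose in 28 of 36 cases (31 higher and 1 lower adjusted over the list alone, median 1.16, adjusted p = 0.018 with an estimated correlation), with OASL 17.3-fold (115 ± 9.003 against 6.62 ± 0.000454), IFIT2 12.1-fold, ISG15 10.2-fold (979 ± 138) and the chemokine CXCL10 at 22.2 ± 6.08 against 0.440 ± 0.547. NF-kB and inflammatory cytokine genes rose in 29 of 36 cases (30 higher and 1 lower adjusted over the list alone, median 0.99, adjusted p = 0.011 with an estimated correlation), with CSF2 4.06-fold (300.2 ± 29.98), CXCL8 3.32-fold (927 ± 97.3) and the adhesion gene ICAM1 3.81-fold. Cell cycle genes fell, 34 of 41 in S phase (also 34 adjusted over the list alone, median -0.63, adjusted p = 0.011 with an estimated correlation) and 35 of 38 in G2/M (37 adjusted over the list alone, median -1.18, adjusted p = 0.064 with an estimated correlation). CDC20 was 3.84-fold, MKI67 4.32-fold, the kinesin gene KIF20A 6.46-fold and PCNA, the sliding clamp of replication, 1.72-fold lower. H2BC4 rose 24.5-fold (21.01 ± 3.55), H2BC5 9.48-fold and H2BC6 9.19-fold, so these histone genes went the same way with all 3 compounds, while 2 of the 13 replication-dependent histones rose (also 2 adjusted over the list alone). Of the 18 response markers 7 rose and 3 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.10), with a median of -0.0153. Nuclear retained and small structured RNAs fell in 3 of 9 cases and rose in 1 (also 3 and 1 adjusted over the list alone, median -0.67, camera adjusted p = 0.21).

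Of the 8 writer genes 6 fell in the libraries labelled I-BET151 (also 6 adjusted over the list alone, median -0.94, camera adjusted p = 8.5e-05, adjusted p = 0.17 with an estimated correlation). METTL14 was 3.03-fold lower (3.50 ± 0.710, adjusted p = 0.0042), VIRMA 2.89-fold (5.78 ± 0.740), RBM15B 2.89-fold (4.76 ± 0.288 against 13.8 ± 0.689), ZC3H13 2.55-fold (4.96 ± 0.0589) and WTAP 1.55-fold (20.5 ± 1.36, adjusted p = 0.0061). METTL3 was 1.64-fold lower (15.99 ± 3.22, log2 fold change -0.69, adjusted p = 0.011), a call lost without DMSO replicate 2 (adjusted p = 0.071). Cytosolic ribosomal protein genes fell in 19 of 53 cases (also 19 adjusted over the list alone, median -0.35, camera adjusted p = 1.1e-06, adjusted p = 0.42 with an estimated correlation), with RPS14 1.96-fold lower (281 ± 1.24 against 550.5 ± 29.7), and DNA repair genes in 16 of 25 (17 adjusted over the list alone, adjusted p = 0.31 with an estimated correlation). POLR2A was 1.88-fold lower (31.0 ± 1.98) and ACAT2, which makes acetoacetyl-CoA for sterol synthesis, 3.67-fold lower. Other rises were SCG5 (34.0-fold, 48.4 ± 6.40 against 1.42 ± 0.497), TFF1 (54.3-fold, 26.0 ± 1.18 against 0.479 ± 0.212), KRTAP2-3 (23.2-fold), MMP1 (6.38-fold) and the immediate early gene EGR1 (6.18-fold). Other falls were NME4 (9.44-fold lower), the detoxifying enzyme GSTP1 (7.05-fold, 40.9 ± 3.11 against 289 ± 3.42), TAGLN2 (6.13-fold) and the splicing regulator PTBP1 (5.88-fold, 35.9 ± 0.994 against 211 ± 0.799), and MYC was 5.73 ± 0.568 (adjusted p = 0.42). In all, 4181 genes passed the threshold, 2069 higher and 2112 lower, against 2001 without DMSO replicate 1 and 1940 without DMSO replicate 2. The count was 2461 when these groups alone were fitted.

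**Figure D3:**
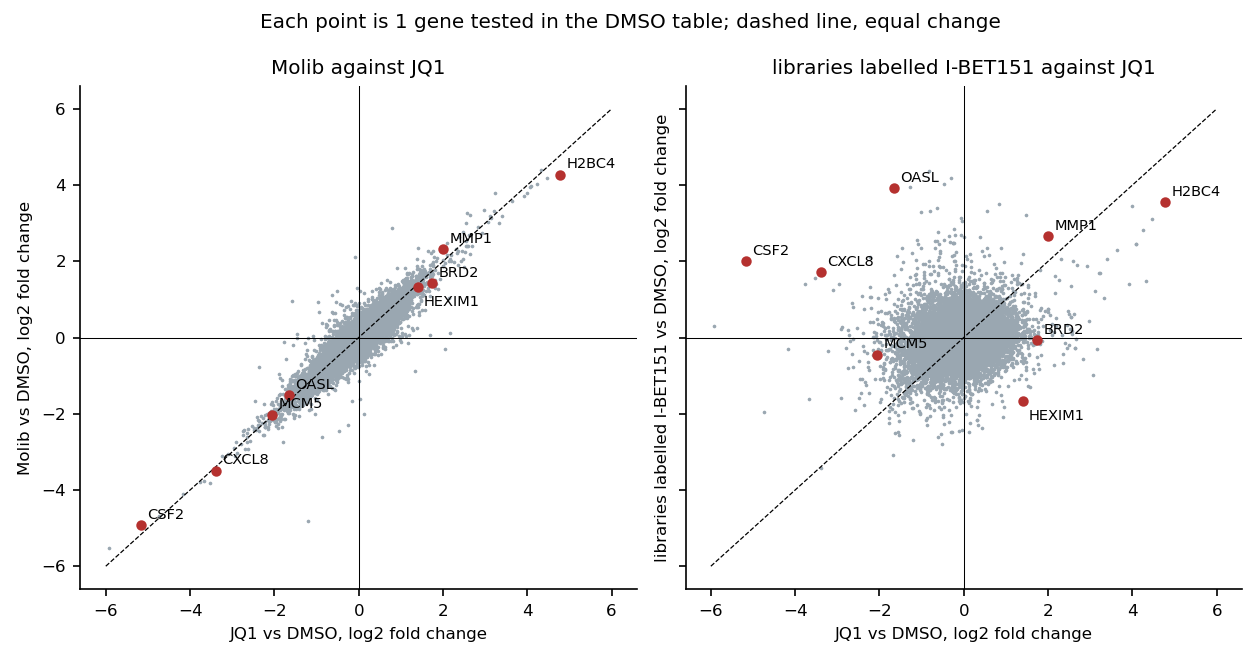
Log2 fold change against DMSO of each gene tested, with JQ1 on the horizontal axis and Molib (left) or the libraries labelled I-BET151 (right) on the vertical axis. The dashed line marks equal change, red points are named genes, and Pearson r across genes was 0.922 on the left and 0.196 on the right.

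Against JQ1 directly, the libraries labelled I-BET151 differed in 6663 genes (3668 higher, 2995 lower). HEXIM1 was 9.03-fold lower (log2 fold change -3.06, adjusted p = 4e-05), BRD2 3.54-fold and POLR2A 3.72-fold lower. CSF2 was 276-fold higher (log2 fold change 7.17, adjusted p = 2.6e-07), CSF3 144-fold (152 ± 12.99), OASL 81.5-fold and CXCL8 35.8-fold. TUBB3, a tubulin of neurons, was 18.1-fold lower, the retrotransposon-derived PEG10 15.4-fold and H3C10 6.80-fold, and MCM5 was 3.24-fold higher. Of 36 NF-kB and inflammatory cytokine genes 34 were higher (also 34 adjusted over the list alone, median 2.42, adjusted p = 0.010 with an estimated correlation), and of 36 interferon-stimulated genes 28 were higher and 1 lower (29 and 1 adjusted over the list alone, median 1.62, adjusted p = 0.062 with an estimated correlation). Against Molib, 6504 genes differed (3532 higher, 2972 lower, or 3205 and 3315 with median scaling), with HEXIM1 8.55-fold lower and CSF2 206-fold higher. Directly, 4 of 8 writer genes were lower than with JQ1 (1 higher and 4 lower adjusted over the list alone, adjusted p = 0.35 with an estimated correlation). METTL14 was 2.00-fold lower than with Molib (adjusted p = 0.019), a call lost without Molib replicate 1 (0.1) or IBET151 replicate 2 (0.0925), and with these groups alone (0.0526), no filter (0.0524) or array weights (0.0525).

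JQ1 and Molib shared 1639 higher and 2555 lower genes, where independent lists of these sizes would share 322 and 628, and 2 genes were called in opposite directions. Their fold changes correlated across genes at r = 0.922, against 0.500 simulated for unchanged groups that share the DMSO libraries, with a covariance of 0.359 against 0.0203. JQ1 and the libraries labelled I-BET151 shared 465 higher and 819 lower genes (300.3 and 434 for independent lists), and 690 genes were called in opposite directions (r = 0.196, covariance 0.0666). For Molib and the libraries labelled I-BET151 the shared genes were 510 and 889 (307 and 432 for independent lists), with 657 opposite (r = 0.223, covariance 0.0774). The 2 DMSO libraries were not split, since each part would hold 1, so part of any excess may come from the shared controls. The same-direction count of JQ1 and Molib went from 4194 to 2457 without DMSO replicate 1, 2342 without DMSO replicate 2, 2613 without library a and 2744 without library b, and the opposite count of JQ1 and the libraries labelled I-BET151 went from 690 to 227, 214, 405 and 406. Taking the mean of the 3 compounds against DMSO, 4722 genes passed the threshold (1996 higher, 2726 lower), or 2089 and 1934 without DMSO replicate 1 and 2. In that mean METTL3 was 18.7 ± 2.68 (log2 fold change -0.48, adjusted p = 0.018, lost without DMSO replicate 1 at 0.0854 or 2 at 0.138), METTL14 5.27 ± 1.90 (-0.93, 0.0072, lost without DMSO replicate 1 at 0.0756) and WTAP 23.1 ± 2.86 (-0.45, 0.0075, lost without DMSO replicate 2 at 0.0809), where the SD spans 6 libraries.

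Knockdown and inhibitors were compared over 13908 genes tested in both tables, by Fisher's exact test (two-sided) on calls per direction. By the same exact test, genes lower in shM3 were also lower with JQ1 in 1012 cases (577 for independent lists, odds ratio 2.82, p = 1.47e-103), with Molib in 1037 (572, 3.04, 1.69e-118) and in the libraries labelled I-BET151 in 725 (372, 3.09, 6.80e-93). Genes higher in both numbered 425 with JQ1 (355, 1.31, 1.22e-05), 496 with Molib (362, 1.61, 5.73e-16) and 618 in the libraries labelled I-BET151 (369.5, 2.28, 1.93e-48). Opposite calls numbered 821, 741 and 615. Spearman's rho of the fold changes was 0.139, 0.174 and 0.185. Genes are not independent replicates, so p and rho are descriptive. The shared higher genes with JQ1 numbered 276 without shM3 replicate 2, 265 and 264 without DMSO replicate 1 and 2, and 257 and 260 without library a and b. With Molib they numbered 319, 296, 298, and 302 and 295 without Molib replicate 1 and 2. In the libraries labelled I-BET151 they numbered 335 and 329, and the shared lower genes 410 and 408, without DMSO replicate 1 and 2.

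**Figure D4:**
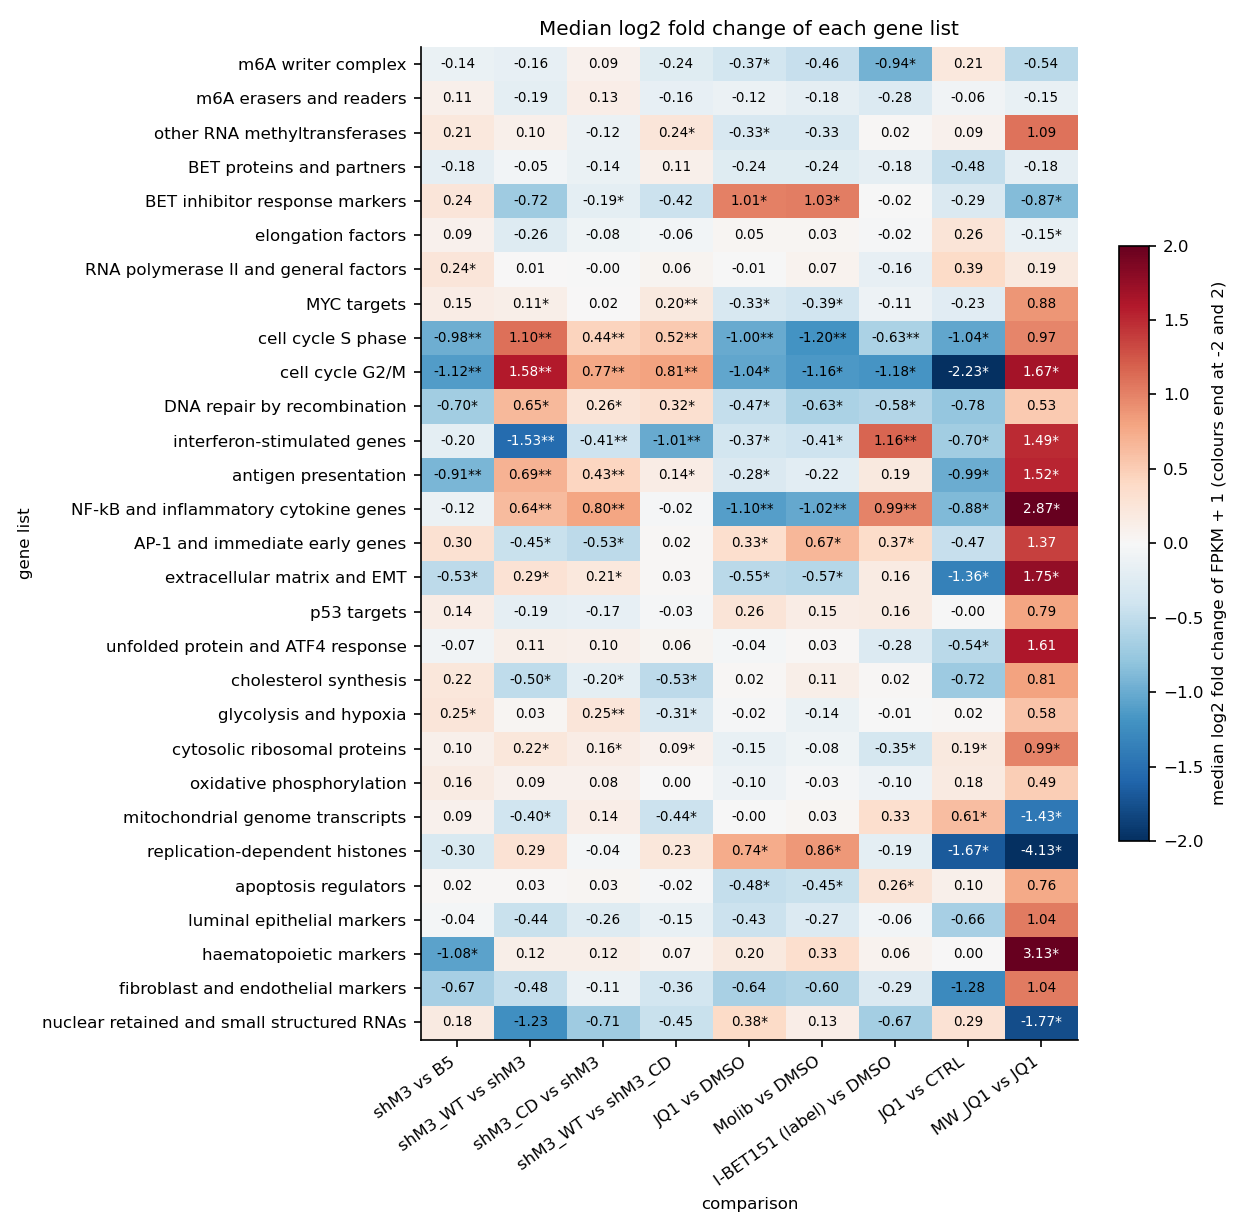
Median log2 fold change of FPKM + 1 for each of the 29 gene lists (vertical axis) in 9 comparisons (horizontal axis), with colours that end at -2 and 2. One star marks a camera adjusted p under 0.05 and a double star one that held with an estimated correlation, such as S phase genes in shM3 against B5 (median -0.98).

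In the CTRL table, JQ1 was set against CTRL and MW_JQ1 against JQ1. No gene passed the threshold between JQ1 and CTRL in limma (0 of 13261, with 2048 at an unadjusted p under 0.05), and without CTRL replicate 2 the count was 492. The authors' deposited table lists 3001 genes at an adjusted p under 0.05. The name of its file sets MW against JQ1, but its fold changes followed JQ1 against CTRL best and are read so here. The libraries of each group differed. METTL3 was 31.2 and 1.18 in CTRL and 11.8 and 0 in JQ1 (adjusted p = 0.80), and of 4951 genes at 10 FPKM or more in every library of the DMSO table, 13.4% and 4.18% lay under 1 FPKM in CTRL and 3.999% and 12.6% in JQ1, but none in MW_JQ1. HEXIM1 was 81.1 ± 5.88 with JQ1 against 57.7 ± 8.04 (adjusted p = 0.41), BRD2 189 ± 52.5 against 93.4 ± 51.5 (0.35) and MYC 24.9 ± 14.95 against 40.6 ± 6.77 (0.54). METTL14 was 6.08 ± 2.42 against 8.64 ± 7.18 (0.96), and WTAP 19.5 ± 8.55 against 31.0 ± 12.1 (0.54). CCNB1 was 20.6 ± 11.2 against 161 ± 113 (0.15), TYMS 69.3 ± 11.5 against 143 ± 5.55 (0.14), CXCL8 7.05 ± 9.44 against 59.5 ± 4.99 (0.22) and the linker histone gene H1-4 196 ± 13.9 against 604 ± 63.0 (0.080).

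Adjusted over the list alone, 22 of 36 G2/M genes were lower with JQ1 than in CTRL (median -2.23, camera adjusted p = 2e-13), 9 of 41 S phase genes (median -1.04), 16 of 42 extracellular matrix and EMT genes (median -1.36) and 11 of 21 replication-dependent histones (median -1.67). In the same way, 10 of 13 mitochondrial genome transcripts were higher (median 0.61, adjusted p = 0.42 with an estimated correlation). None of the 10 lists that camera called held with an estimated correlation (adjusted p = 0.19 for G2/M, S phase, matrix and histone genes), and over all genes no member of any list passed the threshold. The authors' deposited table gave 26 of 36 G2/M genes lower, 23 of 43 matrix genes lower and all 13 mitochondrial transcripts higher. Across the genes tested in both tables, the log2 fold changes of JQ1 in the CTRL and DMSO tables correlated at r = 0.347 (Spearman's rho 0.335, 12604 genes).

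MW_JQ1 was set against JQ1 next. METTL3 was 212 and 234 FPKM in MW_JQ1 against 11.8 and 0 in JQ1 (log2 fold change 5.97, adjusted p = 0.099), and it was called with a pseudocount of 5 (adjusted p = 0.0378) and with array weights (0.0182). RN7SL1 (ENSG00000276168, chromosome 14, 49586580 to 49586878, plus strand), the RNA of the signal recognition particle, was 40.7 ± 24.0 in MW_JQ1 against 46513 ± 5018 in JQ1 (log2 fold change -10.25, adjusted p = 0.00089, or -9.63 and -10.87 without MW_JQ1 replicate 1 and 2). The small nucleolar SNORD3A was 0.152 ± 0.0917 against 6679 ± 649.9, RN7SL5P 1.39 ± 0.00897 against 4825 ± 95.0 and RN7SL4P 1.18 ± 0.772 against 2102 ± 61.6, and these copies of RN7SL1 share sequence with it, so each is uncertain. RNU4-2 was 0.372 and listed at 0 in MW_JQ1 against 642 and 271 in JQ1 (log2 fold change -8.48, or -7.86 and -9.10 without JQ1 replicate 1 and 2). Of 21 replication-dependent histones 14 fell (16 adjusted over the list alone, median -4.13, camera adjusted p = 8.8e-22, adjusted p = 0.15 with an estimated correlation). H1-2 was 4.47-fold lower (151 ± 2.19 against 674 ± 21.7) and H2BC4 7.02-fold lower. Of 13 mitochondrial genome transcripts 11 fell (also 11 adjusted over the list alone, adjusted p = 0.23 with an estimated correlation), with MT-ND5 4.34-fold lower. Of the 5 nuclear retained and small structured RNAs 2 fell (1 higher and 3 lower adjusted over the list alone, median -1.77, adjusted p = 0.27 with an estimated correlation).

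Some messages for inflammatory, matrix and ribosomal proteins were higher in MW_JQ1 than in JQ1, in lists that did not hold with an estimated correlation. Of 33 NF-kB and inflammatory cytokine genes 19 rose (22 adjusted over the list alone, median 2.87, adjusted p = 0.22 with an estimated correlation), with CXCL8 87.4-fold (616 ± 74.5 against 7.05 ± 9.44, log2 fold change 7.09, or 8.80 and 5.38 without JQ1 replicate 1 and 2) and CXCL2 23.1-fold (301 ± 38.8 against 13.04 ± 0.525). Of 3 haematopoietic markers 2 rose (3 adjusted over the list alone, median 3.13, or 2.68 with median scaling, adjusted p = 0.23 with an estimated correlation). Of 42 extracellular matrix and EMT genes 14 rose (23 adjusted over the list alone, adjusted p = 0.22 with an estimated correlation), with PLAU 7.36-fold, the laminin gene LAMB3 6.90-fold and FN1 4.36-fold higher. Of 53 cytosolic ribosomal protein genes 18 rose (28 higher and 2 lower adjusted over the list alone, adjusted p = 0.15 with an estimated correlation), with RPL18 4.86-fold higher. These counts depended on the scaling. With TMM factors 17 inflammatory, 12 matrix and 11 ribosomal genes were higher and 2 ribosomal genes lower, and with median scaling 14, 6 and 3 were higher and 1 ribosomal gene lower. Of 36 G2/M genes 7 rose (9 adjusted over the list alone, adjusted p = 0.27 with an estimated correlation), with AURKA 24.3-fold higher. Antigen presentation genes rose in 6 of 26 cases (9 adjusted over the list alone, adjusted p = 0.22 with an estimated correlation) and interferon-stimulated genes in 7 of 35 (14 adjusted over the list alone, adjusted p = 0.23 with an estimated correlation), with HLA-B 3.14-fold and BST2 4.12-fold higher. With median scaling 4 G2/M, 1 antigen presentation and 4 interferon-stimulated genes were higher and 1 antigen presentation gene lower. NDUFB7, MZT2B, BLVRB and KRT81 were listed at 0 in both JQ1 libraries and at 197 and 209, 82.3 and 94.6, 73.9 and 70.6, and 64.2 and 72.9 FPKM in MW_JQ1. WTAP was 78.5 ± 9.66 against 19.5 ± 8.55 (4.03-fold, adjusted p = 0.047), METTL14 4.65 ± 0.278 (0.85), HEXIM1 50.7 ± 6.09 (0.13, called at 0.047 with TMM factors), BRD2 134 ± 6.69 (0.55) and MYC 6.45 ± 0.144 (0.11, called at 0.0214 without JQ1 replicate 1 and 0.0483 with array weights). IER3, an immediate early gene, rose 5.07-fold.

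In all, 2010 genes passed the threshold between MW_JQ1 and JQ1, 1795 higher and 215 lower. The median gene was 0.75 log2 units higher as deposited, 0.45 with TMM factors and 0.15 with median scaling, and the share of higher calls was 89.3% as deposited and 83.2% and 79.5% with these scalings (1534 and 310, 1371 and 354). The count was 3135 when these groups alone were fitted, 742 with a filter at 5 FPKM, and 226 (144 higher, 82 lower) among genes above 0 in all 6 libraries, a setting chosen after seeing the data. Without MW_JQ1 replicate 1 or 2 it was 50 (3 higher, 47 lower) and 48 (3 higher, 45 lower), while the median gene was still 0.59 and 0.58 higher and CXCL8 6.97 and 7.21. Calls that ended without either were those of CXCL8 (adjusted p = 0.125 and 0.108), CXCL2 (0.0718 and 0.0506), LAMB3 (0.0761 and 0.0976), PLAU (0.232 and 0.201), AURKA (0.389 and 0.417), RPL18 (0.0864 and 0.0736), H2BC4 (0.0963 and 0.0835), MZT2B (0.056 and 0.0688) and BLVRB (0.147 and 0.14). Those of NDUFB7 (0.404 and 0.406), BST2 (0.222 and 0.247), HLA-B (0.263 and 0.384), FN1 (0.295 and 0.359) and WTAP (0.814 and 0.787) ended as well. Without JQ1 replicate 2 the calls of HLA-B (0.0523), WTAP (0.126) and NDUFB7 (0.14) were lost, the last also without JQ1 replicate 1 (0.105). Median scaling ended the calls of WTAP (0.186), BST2, HLA-B, IER3 and FN1. WTAP was also not called with TMM factors (0.0849), a pseudocount of 0.1 (0.0542), the filter at 5 FPKM (0.0654), protein-coding genes alone (0.0555) or genes above 0 in all 6 libraries (0.0849).

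**Figure D5:**
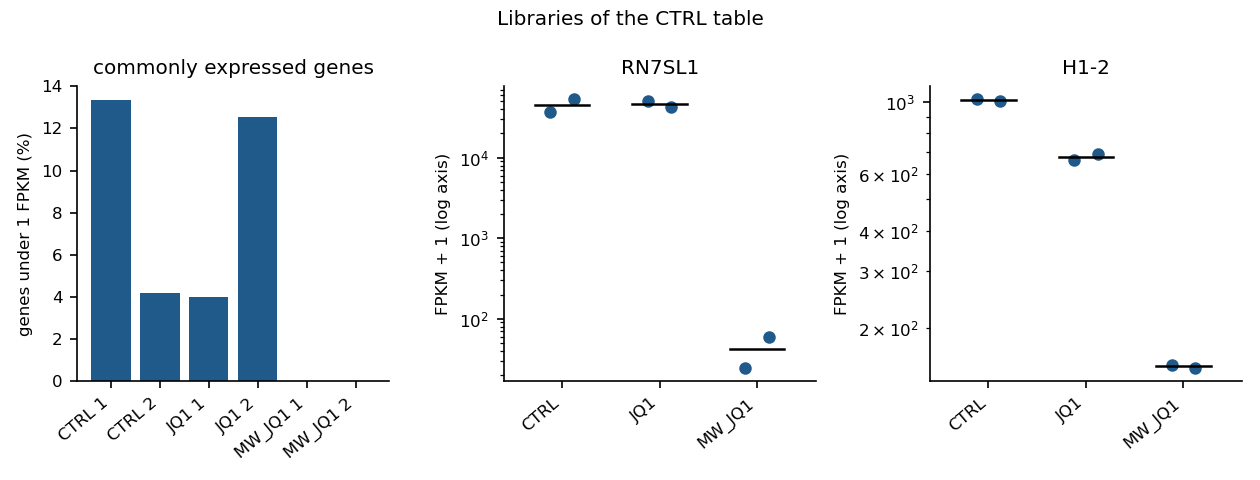
Libraries of the CTRL table. Bars give the percent of 4951 commonly expressed genes under 1 FPKM (3.999 to 13.4% in CTRL and JQ1, 0% in MW_JQ1), and points with mean lines give RN7SL1 and H1-2 (FPKM + 1, log axis), both lower in MW_JQ1 than in CTRL and JQ1.

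MW_JQ1 against CTRL shares the MW_JQ1 libraries, so agreement with the contrast above was not tested. RN7SL1 was 37435 and 52947 in CTRL (log2 fold change -10.19, or -9.57 and -10.81 without MW_JQ1 replicate 1 and 2), H1-2 was 6.73-fold lower in MW_JQ1 (151 ± 2.19 against 1015 ± 5.65), and 19 of 21 replication-dependent histones fell (20 adjusted over the list alone, adjusted p = 0.092 with an estimated correlation). Ribosomal protein genes rose in 25 of 53 cases (32 adjusted over the list alone, adjusted p = 0.092 with an estimated correlation, and 18 and 7 with TMM factors and median scaling), with RPL18 5.53-fold higher. Of 5 nuclear retained and small structured RNAs 2 fell (1 higher and 2 lower adjusted over the list alone, median -0.21), of 13 mitochondrial transcripts 7 (2 higher and 9 lower, 1 lower with median scaling), while 4 of 42 matrix genes rose and 1 fell (also 4 and 1) and 1 of 36 G2/M genes rose (also 1). VIM-AS1 was 517 ± 55.7 against 4.17 ± 5.52 (log2 fold change 7.25, or 5.83 and 8.67 without CTRL replicate 1 and 2), but it is antisense to VIM and its reads cannot be told apart from those of VIM where strand was not used. MYC was 6.45 ± 0.144 against 40.6 ± 6.77 (log2 fold change -2.47, adjusted p = 0.037). In all, 2009 genes passed the threshold, 1760 higher and 249 lower, with 46 (2 higher, 44 lower) and 50 (5 higher, 45 lower) without MW_JQ1 replicate 1 and 2, 3444 without CTRL replicate 2, 710 with a filter at 5 FPKM and 168 (87 higher, 81 lower) among genes above 0 in all 6 libraries. The median gene was 0.61 higher as deposited, 0.42 with TMM factors and 0.14 with median scaling. Without MW_JQ1 replicate 1 or 2 the calls of RPL18 (adjusted p = 0.0592 and 0.0513), VIM-AS1 (0.12 and 0.104) and MYC (0.71 and 0.742) were lost. That of MYC was also lost without CTRL replicate 1 (0.0928) or 2 (0.0858).

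The design asked whether MW reversed the effect of JQ1, but with no gene called between JQ1 and CTRL there was none to follow. Taking instead the 4615 genes called with JQ1 in the DMSO table and tested in the CTRL table, a choice made after seeing the data, 26.0% had the opposite sign in JQ1 against CTRL (5.85% no change), 64.6% in MW_JQ1 against JQ1 and 46.2% in MW_JQ1 against CTRL. Of the 2694 lower genes 85.5% were opposite in MW_JQ1 against JQ1 and 63.5% against CTRL, and of the 1921 higher genes 35.3% and 21.8%. The higher genes had a median of 0.43 in MW_JQ1 against JQ1, where the median of all genes was 0.75, so the 64.6% does not by itself show a reversal. The tables were normalized separately.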

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

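Of the tests in this part, those of a swap with DMSO and of the CTRL and JQ1 libraries as the unusual ones were chosen only after the result was seen. With 2 libraries per group no single library was tested as an outlier.

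The libraries labelled I-BET151 were flagged for 690 calls against DMSO opposite to JQ1 (direct difference also past the threshold), no clear excess over independent lists. HEXIM1, which rose with JQ1, differed by a log2 fold change of -3.06 between them, and CSF2, which fell with JQ1, by 7.17. A swap with the DMSO libraries cannot be told apart. The 18 BET inhibitor response markers had a median of -0.0153 against DMSO with members from -1.66 to 3.56. Members of this list went both ways with JQ1 as well, so its median cannot decide on a swap. HEXIM1 and CSF2 went the way a swap would give, and H2BC4 and the S phase genes went the other way. A different RNA fraction is not settled, since the replication-dependent histones had a median of -0.19 against DMSO with members from -0.88 to 2.05, and cells of another line or type cannot be told apart either, with a highest median of 0.063 among the 3 lists of other cell types, where luminal and haematopoietic markers went both ways. A different response of these cells to this compound at this dose may also account for the pattern and stays untested, as does a wrong label that involves a sample outside the series.

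MW_JQ1 stood apart from CTRL and JQ1 in histone and some structured RNAs and in other lists, none of which held with an estimated correlation. With another RNA fraction or library protocol, MW_JQ1 would lack transcripts without a poly(A) tail, and the replication-dependent histones were lower than the mean of CTRL and JQ1 by a median log2 difference of -5.26. The histone falls reported above rest on the same genes and libraries, so this is not separate support. The fold changes of MW_JQ1 against JQ1 and shM3_WT against shM3 had a Spearman rho of 0.0316 (0.0185 to 0.0445 on leaving out each library). That cannot decide on METTL3 re-expression, which a difference in preparation could hide. The CTRL and JQ1 libraries may be the unusual ones as well, since each had at least 3.999% of genes common in the DMSO table under 1 FPKM against none in MW_JQ1 and at most 0.0202% in a library of the knockdown table. Which of these preparations each library had is not in the labels, and the biological effect of MW on JQ1-treated cells cannot be read from this table if preparation and group coincide.

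The groups shM3_WT and shM3_CD differed directly in 3785 genes. The authors' deposited table, read with doubt as JQ1 against CTRL, holds 3001 genes at an adjusted p under 0.05 (1481 higher, 1520 lower). Limma called 0 genes in that contrast.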

How the results depend on the processing

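The array weights, the protein-coding genes, the genes above 0 in all 6 libraries, the fits without mitochondrial genes and PIDD1 or without the libraries labelled I-BET151, the counts of lists under other scalings, the 13 interval genes, a rule on spread for reading list medians and the 16-fold simulated change were chosen only after results were seen. Alternatives for counts were not run as the values are FPKM. For every change below the cause was not tested, except that a further fold limit keeps fewer genes. A left-out library leaves less information, but some counts rose without 1 library, so that alone does not account for the changes. Over 246 genes and comparisons named in the text, 3442 of 3570 values kept their direction and side of the threshold, 100 were no longer past it, 16 were newly past it and 12 changed direction. Depth limits the lowest genes, since a value near 1 FPKM rests on few fragments that cannot be counted here.

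Direction changed for MYC in shM3 against B5 (-0.39, but 0.84 without B5 replicate 2 and -1.61 without replicate 1), with JQ1 in the DMSO table (0.01, but -0.17 without DMSO replicate 2 and -0.32 without library a, 0.33 without library b) and with Molib (0.15, but -0.035 without DMSO replicate 2, -0.02 without Molib replicate 2 and 0.33 without DMSO replicate 1). It changed for METTL14 in shM3_WT against shM3 (0.20, but -0.030 without shM3_WT replicate 1 and 0.42 without replicate 2), in JQ1 against CTRL (-0.25, but 0.59 without CTRL replicate 2, 0.10 without JQ1 replicate 1 and -1.10 without CTRL replicate 1) and in MW_JQ1 against JQ1 (-0.28, but 0.075 without JQ1 replicate 2 and -0.64 without replicate 1). It changed for MCM5 in Molib against JQ1 (0.034, but -0.024 without Molib replicate 2 and 0.093 without replicate 1). METTL3 changed direction in JQ1 against CTRL (-1.23, but 0.71 without CTRL replicate 1, 0.61 without JQ1 replicate 2 and -3.17 without CTRL replicate 2).

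With a further 2-fold limit, genes past the threshold numbered 1134 in shM3 against B5, 1193 in shM3_WT and 267 in shM3_CD against shM3, 450 between the add-backs, 1315 with JQ1, 1408 with Molib, 889 in the libraries labelled I-BET151 and 620 for the mean of 3 compounds, 2088 and 1999 for I-BET151 against JQ1 and Molib, and 1985 and 1977 for MW_JQ1 against JQ1 and CTRL. The shared calls of JQ1 and Molib were then 1051, and those of JQ1 and I-BET151 177 with 59 opposite. Genes shared with the knockdown were 29 higher and 211 lower with JQ1, 36 and 226 with Molib, and 54 and 107 with I-BET151. The opposite share was 89.6% in shM3_WT, 87.1% in shM3_CD and 48.3% in MW_JQ1 against CTRL.

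Lists called by camera fell from 8 to 3 in shM3 against B5 with an estimated correlation, from 12 to 5 in shM3_WT, 12 to 6 in shM3_CD, 11 to 4 between the add-backs, 15 to 2 with JQ1, 11 to 2 with Molib, 9 to 3 in the libraries labelled I-BET151, 12 to 1 for the mean of 3, 4 to 0 for Molib against JQ1, 11 to 1 and 13 to 1 for I-BET151 against JQ1 and Molib, and 10, 12 and 8 to 0 in the CTRL table. Fry called 15 lists in shM3 against B5, 20 in shM3_WT, 20 with Molib, 21 in I-BET151, 0 between Molib and JQ1, 19 between I-BET151 and JQ1, 6 in JQ1 against CTRL, 20 in MW_JQ1 against JQ1 and 13 against CTRL. Without a filter I-BET151 had 14 lists.

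Same-numbered libraries did not deviate together (correlations of deviations from -0.123 for DMSO and IBET151 to 0.0421), so the numbers do not pair samples. With the replicate number as a block, which leaves out JQ1 of the DMSO table, I-BET151 gave 2724 calls and shared 404 higher genes with the knockdown, and BRD2 in shM3 against B5 was no longer called (adjusted p = 0.0548), nor with its groups alone (0.0905) or array weights (0.064). With the block MYC in MW_JQ1 against CTRL (0.0582) and ZC3H13 (0.0603) and CBLL1 (0.0541) with Molib were not called either, while METTL14 with Molib was (0.0435). MYC in MW_JQ1 against CTRL was also lost with the filter at 5 FPKM (0.06) and above 0 in all 6 libraries (0.0746), CBLL1 with Molib (0.0545) and METTL14 with JQ1 (0.0515) without a filter, and NDUFB7 in MW_JQ1 against JQ1 with a pseudocount of 0.1 (0.0814). Fitting the contrast's groups alone gave 2461 calls in I-BET151, 416 opposite to JQ1 and 340 higher and 429 lower shared with the knockdown, 1 call between Molib and JQ1, 3135 between MW_JQ1 and JQ1, and r = 0.380 for JQ1 in both tables. With a pseudocount of 0.1 JQ1 against CTRL gave 6 calls and r was 0.315. No filter left 451 genes opposite in JQ1 and I-BET151. A filter at 5 FPKM gave 742 and 710 calls for MW_JQ1 against JQ1 and CTRL, protein-coding genes alone 1211 and 1192, and genes above 0 in all 6 libraries 226 and 168. The opposite share of JQ1 calls in MW_JQ1 against CTRL was 45.1% with a pseudocount of 5, 44.3% with the filter at 5, 44.0% with TMM factors, 43.4% with median scaling and 41.9% above 0 in all 6. Array weights gave 2834 calls in I-BET151 and 2 between Molib and JQ1.

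On leaving out each library in turn, calls ranged over 3654 to 4521 in shM3 against B5, 500 to 569 in shM3_CD, 1781 to 1955 between the add-backs, 2854 to 3047 with JQ1, 3056 to 3250 with Molib, 1940 to 4333 in I-BET151, 1934 to 5645 for the mean of 3, 0 to 1 for Molib against JQ1 (1 to 4 lists), 0 to 492 for JQ1 against CTRL, 48 to 2960 for MW_JQ1 against JQ1 and 46 to 3444 against CTRL. Shared calls ranged over 2342 to 2913 for JQ1 and Molib, and 524 to 1295 for JQ1 and I-BET151 with 214 to 603 opposite. Those shared with the knockdown ranged over 257 to 366 higher with JQ1, 295 to 428 higher with Molib, and 329 to 633 higher and 408 to 698 lower with I-BET151. The opposite share ranged from 82.4 to 86.9% in shM3_WT, 77.5 to 83.8% in shM3_CD and 44.0 to 47.3% in MW_JQ1, and r for JQ1 in both tables from 0.262 to 0.342.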

Other observations

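Of the tests in this part, that of a gene copy for MT-ATP6 was set before its result was seen, and the other values were looked up afterwards.

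Camera called none of the following lists when METTL3 was lowered. In shM3 against B5, m6A erasers and readers had 4 genes higher and 2 lower of 12 (also 4 and 2 adjusted over the list alone), other RNA methyltransferases 3 and 1 of 14 (6 and 1), BET proteins and partners 1 and 3 of 8 (also 1 and 3), elongation factors 5 and 1 of 28 (4 and 1), p53 targets 4 and 5 of 26 (also 4 and 5) and the unfolded protein and ATF4 response 6 and 8 of 33 (7 and 8). Oxidative phosphorylation had 8 higher and 3 lower of 43 (6 and 3), and the mitochondrial genome 1 and 1 of 13. Luminal epithelium markers had 3 higher and 2 lower of 12. Interferon-stimulated genes had 4 higher and 15 lower of 39 (6 and 18), among them OASL at 53.6 ± 1.88 against 91.0 ± 0.734 FPKM.

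As given above, POLR2A rose with JQ1 and Molib and fell in the libraries labelled I-BET151. These libraries differed directly from JQ1 (log2 fold change -1.86).

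MT-ATP6, a subunit of ATP synthase, was 673 and 732 FPKM in shM3_CD against 1997 to 3226 in the other knockdown table libraries. It was 3652 in I-BET151 replicate 2 against 436 to 499 in the rest of the DMSO table. Its neighbour MT-ATP8 stayed between 1769 and 2980 in both tables. Reads shared with the near-identical nuclear copy MTATP6P1 could move without changing the sum of both. Their sum differed 6.67-fold between the highest and lowest library, which argues against that as the whole source. How overlapping mitochondrial genes were counted was not tested, and a difference there would coincide with shM3_CD in its contrasts and split the I-BET151 libraries.

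In the authors' deposited table, read as JQ1 against CTRL despite the name of its file, PEG10 had a log2 fold change of 4.13 and SERPINA1 of -5.47, BRD2 of 1.39 (adjusted p = 1.84e-21) and HEXIM1 of 0.70 (8.29e-05), and METTL3 of -0.17 (0.897). Of 8 writer genes none was called there. Of 2575 genes called in the authors' deposited table and tested with JQ1 in the DMSO table, 1227 were called in both, 1081 of them (88.1%) in the same direction. Each CTRL and JQ1 library of the CTRL table correlated with the mean of DMSO, across 12604 genes, at 0.646 to 0.743, and those of MW_JQ1 at 0.911 and 0.913.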
